A study of Mus musculus with 8 samples.

How the data were processed

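Total RNA from 8 samples of mouse adipocytes was labelled with biotin and hybridised to Affymetrix expression arrays, 1 array per sample. The labels describe cells of the F442A preadipocyte line, a fibroblast line that stores fat when differentiated, although another label field gives the line as 3T3L1. Per the labels' protocols, cells at day 6 to 8 of differentiation were infected with an adenovirus carrying the spliced form of Xbp1 (sXBP1) or green fluorescent protein (GFP) and were harvested 4 to 6 days later. These days are given only as ranges, the same for every sample, so whether the groups were matched for them is unknown. Groups and replicate numbers came from the sample titles, 4 samples per group. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

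The values deposited by the authors are linear signal intensity values per probe set, made with MAS5 per the submitters' processing notes; the software version and scaling target are not given in the sources used here. The deposited value table held 22690 probe sets, of which 64 Affymetrix controls were left out and 22626 were tested. The authors' deposited comparison table listed 18394 probe sets with the same per-sample signal values, present or absent calls, a fold and a score. The deposited fold was the ratio of the group means, and the deposited score equalled an unequal-variance t statistic of the linear signals within 0.01 for 99.1% of probe sets. The 4232 non-control probe sets outside it had a median mean signal of 10.5, against 245 for those inside; its filter is not given in the sources used here.

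Gene symbols came from the platform annotation. A single symbol was given for 20380 tested probe sets, several for 691 and none for 1555. The Entrez identifiers of 20351 single-symbol probe sets were found in the mouse RefSeq table of GRCm38.p6, and 0 symbols needed updating. No genome sequence or probe sequence was used, so no coordinates are given. Each of 12393 genes was represented by its probe set with the highest mean over the 8 arrays, among probe sets with 1 symbol, and where not all probe sets of a named gene shared its call, the number that did is given beside it.

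Signals were transformed as log2(signal + 16) and quantile normalized, since the means of the deposited signals after trimming 2% at each end differed between arrays, from 494 to 577. The rule that chose this normalization for unscaled values was fixed before the data were examined. Folds are on the log2(signal + 16) scale, which understates changes of dim genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided), with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. Log2 changes are sXBP1 minus GFP and are given with their standard error. Where a probe set past the threshold was called present on none of the 4 arrays of 1 group, the change is given as at least N-fold. The bound sets the brighter group's mean against the mean of, per array, the higher of the probe set's own value and the lowest signal among probe sets called present on all 4 arrays of that group. Where the probe set's own values were the higher, the bound equals the plain fold. It allows for detection only and is not a confidence limit, so 95% limits are given with it. Figures were drawn with matplotlib 3.10.9.

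Gene lists were fixed before the data were examined: 25 lists with 567 different measured genes. Each list was described by its members past the threshold over all tested probe sets, and again with p-values adjusted over the list alone. Lists were tested on representative probe sets with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 25 lists. Camera compares a list with other genes; fry tests only whether its members move, on balance, one way.

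The genes named were chosen by a rule fixed before the data were examined. It took Xbp1, then the 8 largest rises and 8 largest falls past the threshold with non-overlapping groups and a mean in the higher group above the median of the tested probe sets. It also took the 2 members of each list with the smallest p (3 for 8 of the lists) and 10 genes fixed by name. Of the latter, Prlr was not analysed here. Other named genes are said to have been chosen after their values were seen.

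On simulated data with 200 of 22626 probe sets changed, the fit recovered 81% of those changed by 1 on the log2 scale and 32% of those changed by 0.5, and 4.24% of its calls were false. In the real data 5543 probe sets were called, and the simulated values were not quantile normalized again. These rates therefore need not hold for the real fit. A simulated list shift of 0.4 was called at the preset correlation, with 0 of the other lists. The simulated genes varied independently, whereas estimated correlations within the real lists reached 0.394. The simulation therefore does not measure false list calls in these data. The number of arrays limits the precision.

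Alternatives were other pseudocounts (1 and 64), leaving out the dimmest 40% of probe sets, median centring, eBayes without trend or with robust estimation, array weights, a replicate block, leaving out each replicate, stricter thresholds, the mean of all probe sets per gene and the estimated correlation. Added after the data were seen were the values as deposited, probe sets present on all 4 arrays of a group, and fits without sXBP1 arrays 3 and 4 or without sXBP1 arrays 1 and 2. The comparison table held no p-values and no other scale, so 2 alternatives based on it, set before the data were examined, were not run. Another 8 gene lists were composed after an exploratory fit had been seen. The peroxisome list among them was corrected after its result was seen, when a gene placed there in error was replaced by 2 peroxisomal membrane genes. Dpt, which is not a small leucine-rich protein, was likewise removed from the list of such proteins after its result was seen. The rule for judging these lists was then tightened to require the estimated correlation too, and the rule for fibroblast markers was likewise tightened to require every scaling. The rule for macrophage markers was limited to those present on all sXBP1 arrays, the saturation test of the dimmer Xbp1 probe sets was replaced, and changes of sign in values past no threshold were counted as such, after the results had been seen.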

Results

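Expression was measured on 8 arrays, 4 from cultured mouse adipocytes infected with adenovirus carrying sXBP1 and 4 from cells infected with GFP virus. The labels name both F442A and 3T3L1 as the line. Xbp1 encodes a transcription factor whose messenger RNA is spliced by the kinase and nuclease IRE1 during endoplasmic reticulum (ER) stress. The comparison addressed which transcripts differ in adipocytes given the spliced form. Median signal was 143 ± 8.53 (SD, n = 4) on GFP arrays and 128.2 ± 9.15 (SD, n = 4) on sXBP1 arrays (two-sided exact permutation p = 0.0857). The Gapdh 3' to 5' signal ratio, a measure of RNA integrity, was 0.816 ± 0.005 in GFP and 0.783 ± 0.013 in sXBP1 samples (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows). The actin ratio was 1.42 ± 0.019 and 1.38 ± 0.047 (two-sided exact permutation p = 0.143). Correlations between arrays, across 11903 probe sets that are not independent replicates, were 0.991 to 0.995 within GFP, 0.987 to 0.994 within sXBP1 and 0.952 to 0.972 between groups.

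The overexpressed gene, Xbp1, did not differ on any of its 4 probe sets. The brightest gave a signal of 9888 ± 283 (SD, n = 4) in GFP and 10319 ± 418 in sXBP1 samples, a log2 change of 0.07 ± 0.04 (limma adjusted p = 0.271). The others changed by 0.08, -0.02 and 0.06. After median centring Xbp1 changed by 0.21 (adjusted p = 0.0307). Where these probe sets lie relative to the viral insert was not analysed here, so they do not check the labels.

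**Figure D1:**
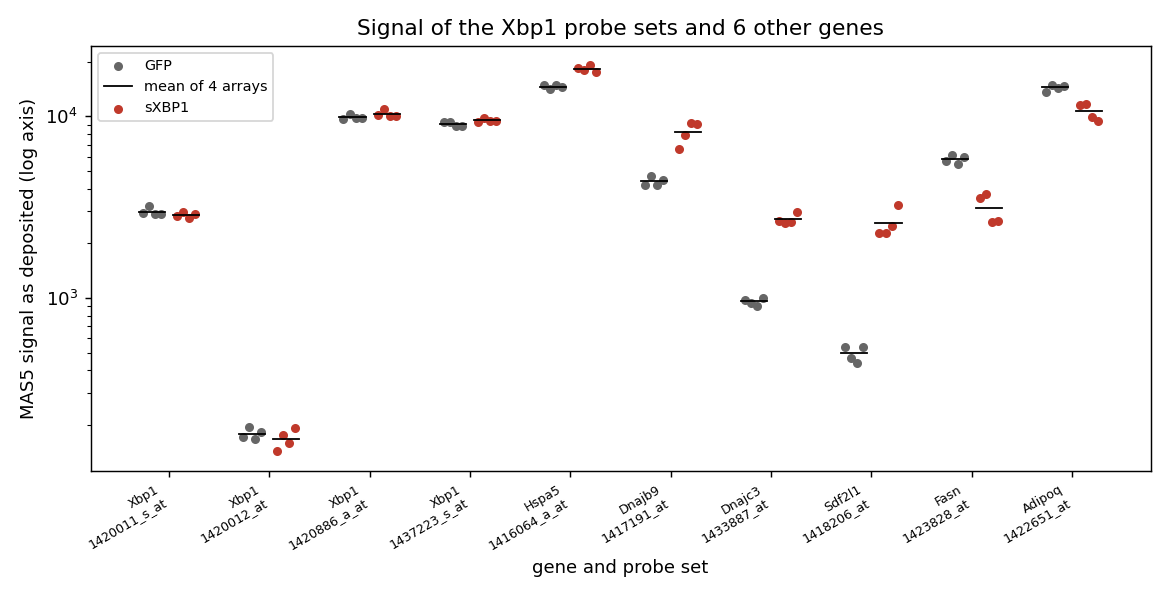
MAS5 signal as deposited, on a log axis, of the 4 Xbp1 probe sets and 6 other genes; each point is 1 array and each line the mean of 4. The Xbp1 groups overlap or lie close together, while every sXBP1 array lies above every GFP array for Sdf2l1 and Dnajc3 and below for Fasn and Adipoq.

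The 5 lists of ER and secretory pathway genes were higher in sXBP1 cells with camera at the preset and at the estimated correlation. Inflammatory genes were higher, and genes of fat and mitochondrial metabolism lower, with camera at the preset correlation but not at the estimated one (adjusted p = 0.0829 for the NF-kB list and 0.185 to 0.361 for the others). Fry, which does not compare a list with other genes, passed for 22 of 25 lists, upward for NF-kB (adjusted p = 2.2e-04) and downward for the 4 fat and mitochondrial lists (adjusted p = 2.8e-04 to 0.0099). Of 12393 genes, 1602 were higher, 1784 were lower and 9007 did not pass the threshold (limma, adjusted p under 0.05). At least 2-fold changes were found for 184 higher and 73 lower genes. Among 22626 probe sets, 2601 were higher and 2942 lower, so 46.9% of the 5543 changed probe sets were higher. That share was 33.4% with values as deposited and 60.7% after median centring. The median change of all tested probe sets was -0.02 with quantile normalization, -0.07 as deposited and 0.07 after median centring, so the balance of rises and falls depends on the scaling.

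The largest rises were in Ighm, Csn3, Evi2a, Rnf183, Lpin3, Ramp3, Bcat1 and Lyz1. Ighm, the immunoglobulin mu heavy chain, was called present on none of the 4 GFP arrays and was at least 21.7-fold higher in sXBP1 samples (adjusted p = 1.5e-05), but only 2 of its 11 probe sets shared the call. Csn3, the milk protein kappa-casein, was at least 14.0-fold higher (adjusted p = 1.7e-05), on 1 of 2 probe sets. Rnf183, a ubiquitin ligase, and Ramp3, a receptor activity-modifying protein, were called present on none of the GFP arrays and were at least 8.04-fold and 9.90-fold higher. The lower 95% confidence limits of the log2 changes were 3.68 for Ighm, 3.19 for Csn3, 2.97 for Rnf183 and 2.83 for Ramp3. Lpin3, a phosphatidate phosphatase, rose by 3.49 ± 0.15 and Bcat1, the cytosolic branched-chain aminotransferase, by 3.19 ± 0.14 (adjusted p = 6.1e-07 and 7.8e-07). Evi2a rose by 3.71 ± 0.23. Lyz1 rose by 3.19 ± 0.30 on 2 of 3 probe sets, although its probe set may also detect the near-identical Lyz2.

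The largest falls were in Mb, Mcam, Ogn, Acaa1b, Car2, Ubd, Cavin2 and Id4. Mb, myoglobin, was called present on none of the 4 sXBP1 arrays and was at least 4.08-fold lower (adjusted p = 4.7e-04), while its other probe set changed by 0.63. The 95% confidence interval of the log2 change of Mb was -2.65 to -1.40. Acaa1b, a peroxisomal thiolase, fell by 1.73 ± 0.11, and Cavin2, a component of caveolae, fell by 1.58 ± 0.15. Ogn, a small leucine-rich matrix proteoglycan, fell by 1.74 ± 0.12, and Id4, an inhibitor of DNA binding, fell by 1.55 ± 0.14. Mcam fell by 1.80 ± 0.34, Car2 fell by 1.68 ± 0.20 and Ubd fell by 1.67 ± 0.12.

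**Figure D2:**
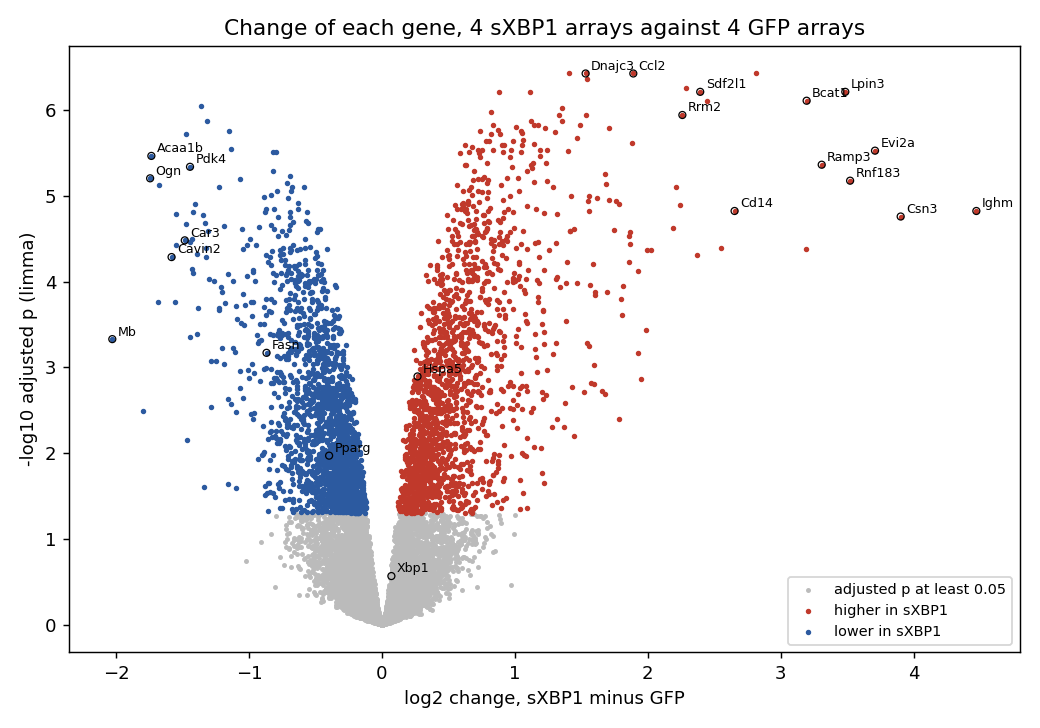
Log2 change (sXBP1 minus GFP) of each of 12393 genes against -log10 of the limma adjusted p; red genes were higher and blue genes lower past the threshold. Ighm and Csn3 lie farthest to the right and Mb farthest to the left, and Xbp1 lies among the genes that did not pass.

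Genes for protein folding, quality control and traffic in the ER rose together. Of 36 ER chaperone and oxidative folding genes, 26 rose and 0 fell (29 and 0 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 1.4e-19). Sdf2l1, an ER chaperone cofactor, rose by 2.39 ± 0.10, Fkbp11, a prolyl isomerase, by 2.29 ± 0.09 on 2 of 3 probe sets and Dnajc3, a cochaperone of BiP, by 1.53 ± 0.06. Hspa5, which encodes BiP, rose by 0.27 ± 0.04 from a signal of 14594 near the top of the range, and Dnajb9 rose by 0.90 ± 0.08. Of 28 ER-associated degradation genes, 22 rose and 1 fell (23 and 1 adjusted over the list alone; median 0.41, camera adjusted p = 2.2e-14). The gene that fell was called present on no array. Edem2 rose by 1.41 ± 0.05, Selenos by 1.33 ± 0.07 and Rnf5 by 0.82 ± 0.05.

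Genes for entry into the ER, glycosylation and vesicle transport also rose. Of 22 genes for protein entry into the ER, 19 rose and 0 fell (19 and 1 adjusted over the list alone; median 0.68, camera adjusted p = 1.2e-18). Among them were Sec11c of the signal peptidase at 1.23 ± 0.07, Srprb of the signal recognition particle receptor at 1.18 ± 0.06 and Ssr2 at 0.82 ± 0.04. Of 28 N-glycosylation genes, 25 rose and 0 fell (26 and 0 adjusted over the list alone; median 0.55, camera adjusted p = 8.9e-18). Mgat2 rose by 1.54 ± 0.06, and the oligosaccharyltransferase genes Rpn1 and Ddost by 0.97 ± 0.06 and 0.79 ± 0.05. Of 44 ER-Golgi vesicle transport genes, 35 rose and 1 fell (39 and 1 adjusted over the list alone; median 0.40, camera adjusted p = 9.7e-21), with Preb at 1.47 ± 0.08, Sec23b at 1.35 ± 0.07 and Tmed3 at 0.89 ± 0.05. With an estimated correlation these 5 lists kept adjusted p = 0.0251, 0.0248, 0.0457, 0.012 and 0.0251, in the order given. Their 158 genes averaged 0.53, 0.51, 0.60 and 0.59 above the GFP mean on sXBP1 arrays 1 to 4.

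Sensors and transcription factors of the unfolded protein response moved less uniformly. Of 13 measured, 6 rose and 1 fell, with the same counts adjusted over the list alone (median 0.15, camera adjusted p = 0.0054; adjusted p = 0.076 with an estimated correlation). The median was 0.092 without GFP replicate 4 and 0.25 without sXBP1 replicate 4. Atf6 rose by 0.90 ± 0.05, Eif2ak3, which encodes the kinase PERK, by 0.79 ± 0.05 on 1 of 3 probe sets, and Creb3 by 0.69 ± 0.06 on 3 of 4. Ern1, which encodes IRE1, changed by -0.12 ± 0.16 (adjusted p = 0.688). Its signals were dim, 25.95 in GFP and 22.1 in sXBP1 samples, and it was called present on 2 of 4 sXBP1 arrays. Of 34 genes of the ATF4 and CHOP response, 8 rose and 5 fell (9 and 8 adjusted over the list alone; median -0.04, mean 0.019, camera adjusted p = 0.901). Its members included Phgdh and Vldlr, which fell by 0.80 ± 0.05 and 0.70 ± 0.05, Vldlr on 3 of 4 probe sets. Atf4 rose by 0.31 ± 0.04 on 1 of 3 probe sets but did not pass with the mean of all probe sets (adjusted p = 0.505). Ddit3, which encodes CHOP, changed by 0.06 ± 0.05 (adjusted p = 0.42) and passed after median centring (0.19). Of 7 IRE1 RNA-decay substrates, 1 rose and 2 fell (1 and 3 adjusted over the list alone; median -0.11, camera adjusted p = 0.141), with Hgsnat at 0.90 ± 0.17 and Pdgfrb at -0.76 ± 0.07 on 1 of 2 probe sets.

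Adipocyte and lipid genes were mostly lower in sXBP1 samples. Of 28 adipocyte identity genes, 16 fell and 3 rose (17 and 3 adjusted over the list alone; median -0.28, camera adjusted p = 1.4e-04; adjusted p = 0.361 with an estimated correlation). Car3 fell by 1.48 ± 0.13, Adipoq, adiponectin, by 0.49 ± 0.08 and Pparg, the master regulator of fat cell differentiation, by 0.40 ± 0.09. Fabp4 changed by -0.02 ± 0.04 near the top of the range, with 3 of 4 probe sets not passing, and its call differed in the mean of all probe sets (-0.31, adjusted p = 0.029). Cebpd rose by 0.72 ± 0.09 and Angptl4 by 0.30 ± 0.04, each on 1 of 2 probe sets, and neither passed with the mean of all probe sets (adjusted p = 0.105 and 0.0848). Of 26 fatty acid and triglyceride synthesis genes, 15 fell and 2 rose (17 and 2 adjusted over the list alone; median -0.33, camera adjusted p = 5.8e-06; adjusted p = 0.251 with an estimated correlation). Fasn, fatty acid synthase, fell by 0.87 ± 0.13, Acss2 by 0.88 ± 0.12, Thrsp by 1.42 ± 0.15 and Pck1 by 1.31 ± 0.11, the last on 1 of 2 probe sets.

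Genes of fat breakdown and of the respiratory chain were lower too. Of 25 lipolysis and fatty acid oxidation genes, 16 fell and 1 rose (16 and 2 adjusted over the list alone; median -0.49, camera adjusted p = 1.4e-06; adjusted p = 0.251 with an estimated correlation). Pdk4 fell by 1.44 ± 0.10 and Acadl by 0.68 ± 0.05, the latter on 1 of 2 probe sets and not with the mean of all probe sets (adjusted p = 0.221). Of 31 oxidative phosphorylation genes, 24 fell and 1 rose (25 and 2 adjusted over the list alone; median -0.31, camera adjusted p = 9.6e-10; adjusted p = 0.185 with an estimated correlation). Cox7a1 fell by 1.22 ± 0.09 and Ndufb8 by 0.56 ± 0.05. These lists averaged lower on sXBP1 arrays 3 and 4 than on arrays 1 and 2: adipocyte identity lay at -0.48 and -0.59 against -0.23 and -0.25. The Gapdh 3' to 5' ratio, lower in sXBP1 than in GFP samples, was 0.775 and 0.777 on sXBP1 arrays 1 and 2 and 0.778 and 0.802 on arrays 3 and 4.

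Inflammatory genes were higher in sXBP1 samples. Of 26 NF-kB and acute-phase genes, 13 rose and 0 fell, with the same counts adjusted over the list alone (median 0.43, camera adjusted p = 3.4e-06; adjusted p = 0.0829 with an estimated correlation). The chemokines Ccl2 and Ccl7 rose by 1.89 ± 0.07 and 2.22 ± 0.16. Of 18 macrophage and leukocyte markers, 4 rose and 0 fell, with the same counts adjusted over the list alone (median 0.17, camera adjusted p = 0.0348; adjusted p = 0.282 with an estimated correlation), and without sXBP1 replicate 3 the list did not pass (median 0.11, camera adjusted p = 0.0569). Cd14, a coreceptor for lipopolysaccharide, rose by 2.65 ± 0.21 and the lysosomal glycoprotein Cd68 by 1.79 ± 0.14. These lists also stood higher on sXBP1 arrays 3 and 4 than on arrays 1 and 2, the NF-kB list at 0.80 and 0.68 against 0.49 and 0.47 and the macrophage list at 0.58 and 0.54 against 0.34 and 0.28. Across 11903 probe sets, the slope of each array's change on that of the other 3 sXBP1 arrays was 0.795, 0.775, 1.15 and 1.12 for arrays 1 to 4. Of 29 interferon response genes, 3 rose and 4 fell, with the same counts adjusted over the list alone (median -0.01, camera adjusted p = 0.586). Oas1a was at least 3.03-fold higher (95% confidence interval of the log2 change 1.19 to 2.01), called present on 2 of 4 sXBP1 arrays, and Gbp2 fell by 0.76 ± 0.08.

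**Figure D3:**
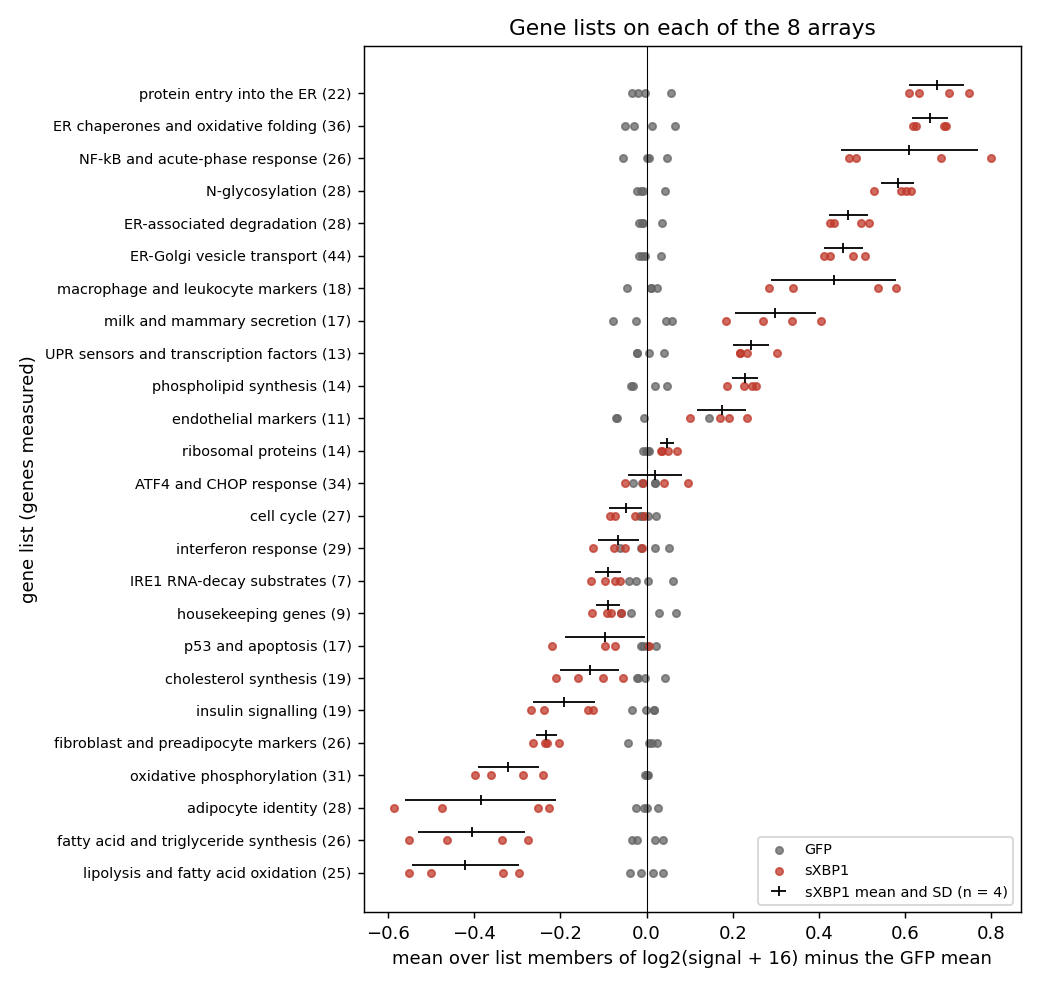
Mean over each list's members of log2(signal + 16) minus the GFP mean, 1 point per array, with the sXBP1 mean and SD (n = 4) above; the number of genes measured stands in parentheses. Protein entry into the ER averages 0.67 and lipolysis and fatty acid oxidation -0.42 on sXBP1 arrays.

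Other lists changed less or split. Of 26 fibroblast and preadipocyte markers, 2 rose and 11 fell, with the same counts adjusted over the list alone (median -0.10, camera adjusted p = 0.0158; adjusted p = 0.251 with an estimated correlation). Acta2, smooth muscle actin, fell by 1.06 ± 0.07 on 1 of 2 probe sets and Postn by 0.62 ± 0.06. The list did not pass after median centring (median -0.01, camera adjusted p = 0.151), and its median was -0.061 without sXBP1 replicate 4. Of 19 insulin signalling genes, 1 rose and 6 fell (1 and 8 adjusted over the list alone; median -0.08, camera adjusted p = 0.0348; adjusted p = 0.251 with an estimated correlation). The list did not pass without GFP replicate 1 (camera adjusted p = 0.0536), and its median was -0.13, -0.15 and -0.14 without GFP replicate 3, sXBP1 replicate 3 and sXBP1 replicate 4. Socs3, a suppressor of cytokine signalling, rose by 1.17 ± 0.14, and the insulin receptor adaptor Grb14 fell by 1.02 ± 0.09. Of 11 endothelial markers 0 rose and 0 fell, also adjusted over the list alone (median 0.08, camera adjusted p = 0.312), with Flt1 at 0.32 ± 0.13 (adjusted p = 0.116; 1 of its 3 probe sets shared this outcome, and the mean of all probe sets passed at 0.39). However, 8 of these 11 markers were present on no GFP array or not listed. Tek was called present on none of the GFP arrays and 1 sXBP1 array, with dim signals of 6.78 in GFP and 17.6 in sXBP1 samples. It changed by 0.54 ± 0.21 and did not pass (adjusted p = 0.0862), except after median centring and without sXBP1 replicate 1 (adjusted p = 0.0359 and 0.0407).

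Of 14 phospholipid synthesis genes 4 rose and 2 fell (4 and 4 adjusted over the list alone), with a median of -0.07 but a mean of 0.23, carried by Lpin3 (camera adjusted p = 1.0). Chpt1 fell by 0.64 ± 0.07. Of 19 cholesterol synthesis genes 1 rose and 5 fell, with the same counts adjusted over the list alone (median -0.08, camera adjusted p = 0.103), with Ebp at 1.14 ± 0.07 and Dhcr7 at -1.12 ± 0.12. Of 27 cell cycle genes 5 rose and 11 fell (7 and 11 adjusted over the list alone; median -0.27, camera adjusted p = 0.311). Rrm2, a subunit of ribonucleotide reductase, rose by 2.26 ± 0.11 on 3 of 3 probe sets, and Ube2c fell by 0.88 ± 0.07. Of 17 p53 and apoptosis genes 2 rose and 4 fell, with the same counts adjusted over the list alone (median -0.04, camera adjusted p = 0.421), with Gadd45b at -0.55 ± 0.07 on 1 of 3 probe sets and Bcl2l11 at -0.73 ± 0.13 on 3 of 5. Of 17 milk and mammary secretion genes 4 rose and 1 fell, with the same counts adjusted over the list alone (median 0.08, camera adjusted p = 0.312), including Csn3 and Xdh, the latter at 0.84 ± 0.04. Among these 17 genes, 11 were present on no GFP array or not listed. Of 14 ribosomal protein genes 1 rose and 0 fell (median 0.06, camera adjusted p = 0.156), with Rps3 at 0.16 ± 0.03 and Rpl8 at 0.07 ± 0.04. Rps3 did not pass as deposited or without a trend (adjusted p = 0.0758 and 0.0685), and Rpl8 passed after median centring (adjusted p = 0.0264). Of 9 housekeeping genes 1 rose and 3 fell (median 0.02, mean -0.09, camera adjusted p = 0.586), with Sdha at -0.36 ± 0.06 and Tfrc at -0.75 ± 0.10 on 2 of 3 probe sets. Both counts were the same adjusted over the list alone.

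In the authors' deposited table, 5402 of the changed probe sets were listed and 5402 of them had the same direction; the remaining 141 were not listed. Log2 folds in the authors' deposited table correlated with those of the limma fit across 18394 probe sets (Pearson r = 0.918, Spearman rho = 0.970). Both come from the same arrays, and probe sets are not independent replicates. The authors' deposited table gave a direction to all 18394 listed probe sets, without a threshold. It listed 6837 as higher in sXBP1 and 11557 as higher in GFP, which are not counts of changed probe sets.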

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

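All tests of explanations in this part were written down after the results were seen, including the splits of the samples, which had been planned. The 5543 changed probe sets were compared with other groupings of the arrays: 1 of the 35 splits into 4 and 4, the real one, gave as many, and the highest of the others gave 0. The real grouping thus stood apart from every other. Its share, 0.0286, is the smallest the design allows and does not exclude a chance assignment of these 8 arrays. The other splits mix the 2 groups, so any 2 distinct sets of arrays could give this outcome. A chance difference between 2 cultures cannot be excluded either, since the labels do not say that the replicates were separate cultures.

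Xbp1 probe sets were not higher in the sXBP1 arrays. The genes of the ER and ER-Golgi lists had a median change of 0.54, with every sXBP1 array above every GFP array. This direction argues against exchanged group labels only if spliced Xbp1 is taken to raise these genes, which these data cannot check. The separation of the arrays alone would also hold with exchanged labels. For the 2 dimmer Xbp1 probe sets, with GFP signals of 2989 and 179, saturation at that signal level is argued against by 34 of 1059 probe sets at GFP levels above theirs and below the brighter Xbp1 ones, which rose at least 1.5-fold. For the 2 brighter ones saturation cannot be told apart from no change, since 0 of 233 probe sets at least as bright rose 1.5-fold. Saturation of single probes, and whether the probe sets lie outside the viral sequence, were not tested and stay open.

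Adipocyte, lipid and mitochondrial lists were lower in the sXBP1 arrays. Scaling as the whole cause is argued against by the median closest to 0 among the 4 lists after median centring or as deposited, -0.19, with each list still past the set test at the preset correlation. Arrays 3 and 4 alone are argued against by the median closest to 0 without them, -0.21. A lower share of differentiated cells cannot be told apart from lower expression within adipocytes: fibroblast markers had a median of -0.10, but 23 of 26 were already present on all GFP arrays, and the median was -0.01 after median centring and -0.061 without sXBP1 replicate 4. An effect of sXBP1 and a difference in RNA integrity also stay open.

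Cd14, Cd68 and Lyz2 were higher in the sXBP1 arrays; Lyz2, at 1.92 ± 0.28, was singled out after its value was seen. Macrophages among the sXBP1 cells, which the labels give as a cultured line, were not told apart from induction within adipocytes by these values. The other 15 markers had a median of 0.053 and an upper quartile of 0.20, and 1 of them rose. However, 8 of them were never called present on sXBP1 arrays, and whether their probe sets could report a rise is unknown. The 2 of the 15 markers present on all 4 sXBP1 arrays, Csf1r and Adgre1, also named after their values were seen, stood at 0.49 ± 0.14 (adjusted p = 0.0239) and -0.12 ± 0.16. The rule, limited to such markers after the results had been seen, asked for more of them and so could not decide.

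Of 222 groups of 4 arrays examined, 11 had an array far from the others (gap over range above the 95% critical value), and chance gives about 1 in 20. In GFP samples these were Rnf183 on array 3 (0.830), Mgat2 on array 4 (0.838), Tmed3 on array 1 (0.870), Cox7a1 on array 3 (0.950), Pdk4 on array 2 (0.844) and Id4 on array 1 (0.947). Fabp4 on GFP array 3 gave a ratio of 1, because quantile normalization gave its other GFP arrays equal values. In sXBP1 samples they were Angptl4 on array 1 (0.877), Phgdh on array 3 (0.835), Pck1 on array 1 (0.896) and the Gapdh 3' to 5' ratio on array 4 (0.889).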

How the results depend on the processing

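The alternatives added after the data were seen are the values as deposited, probe sets present on all 4 arrays of a group, and fits without sXBP1 arrays 3 and 4 or 1 and 2. Of 1695 values of 81 named genes, 1678 kept direction and call, 6 passed the threshold only under the alternative, 6 lost it and 5 changed sign, all of genes past the threshold in neither setting. Lost were Rps3 as deposited (0.14) and without a trend (0.16), and with the mean of all probe sets Cebpd (0.41), Atf4 (0.093), Angptl4 (0.14) and Acadl (-0.22). Passing were Tek (0.71), Rpl8 (0.18) and Ddit3 (0.19) after median centring, Tek without sXBP1 replicate 1 (0.67), and Flt1 (0.39) and Fabp4 (-0.31) with the mean of all probe sets. Signs changed for Fabp4 as deposited (0.013) and after median centring (0.16), and Ern1 with the mean of all probe sets (0.054), without sXBP1 arrays 3 and 4 (0.025) and without sXBP1 replicate 4 (0.022; -0.18 to 0.022 leaving out 1 replicate). Medians of lists that passed in neither setting also changed sign. After median centring these were ATF4 and CHOP (0.060), interferon (0.072) and p53 (0.019), and without sXBP1 arrays 1 and 2, ATF4 and CHOP (0.019) and p53 (0.079). Housekeeping genes turned to -0.025 with the mean of all probe sets and -0.012 without arrays 3 and 4. Leaving out 1 replicate, medians ran from -0.046 to 0.035 for housekeeping, -0.086 to 0.012 for p53, -0.15 to 0.0060 for interferon, -0.0018 to 0.12 for milk genes, 0.0050 to 0.21 for endothelial markers, -0.14 to -0.076 for cholesterol synthesis, -0.054 to -0.011 for ATF4 and CHOP, -0.099 to -0.057 for phospholipid synthesis, 0.092 to 0.25 for UPR sensors and -0.11 to -0.061 for fibroblast markers. As deposited, 1600 probe sets and 1012 genes were higher, and ribosomal proteins passed at 0.071. Median centring gave 3379 higher and 2191 lower probe sets, turning the balance; Xbp1 passed at 0.21 and ribosomal proteins at 0.22, and the fibroblast list did not pass at -0.0091. At least 2-fold changes held for 289 higher and 120 lower probe sets (184 and 73 genes), and at adjusted p under 0.01, 1705 probe sets and 1036 genes were lower; fewer pass by construction. Insulin signalling did not pass without the dimmest probe sets (-0.14), with the mean of all probe sets (-0.11), with present probe sets only (-0.21) or without sXBP1 arrays 3 and 4 (-0.20), and ranged from -0.15 to -0.084 leaving out 1 replicate, lost without GFP replicate 1. Macrophage markers did not pass without arrays 3 and 4 (0.13) and ranged from 0.11 to 0.19, lost without sXBP1 replicate 3. Cholesterol synthesis passed without arrays 1 and 2 (-0.16). With an estimated correlation these lists, at the same medians, lost their call: UPR sensors (0.15), adipocyte identity (-0.28), fatty acid and triglyceride synthesis (-0.33), lipolysis and oxidation (-0.49), oxidative phosphorylation (-0.31), insulin signalling (-0.080), NF-kB (0.43), fibroblast (-0.10) and macrophage markers (0.17). The cause was not tested, apart from the thresholds.

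Leaving out 1 replicate gave 2248 to 2549 higher and 2344 to 2830 lower probe sets. Without sXBP1 arrays 3 and 4 there were 2029 higher and 2181 lower, and without arrays 1 and 2, 2653 and 3043. Whether replicate numbers pair the samples stays open. Correlations of deviations were 0.112 and 0.103 for replicates 1 and 4, above the cutoff of 0.1 set for pairing. They were 0.03 and -0.09 for replicates 2 and 3, and 2 of 4 matched best with their own number. The fit with a replicate block gave 2427 higher and 2656 lower probe sets (1509 and 1617 genes). The comparisons set before the data were examined that needed the authors' p-values or values on another scale were not run, since the table held neither. Dim signals limit several lists, in which many genes were present on no GFP array or not listed. Such genes were 11 of 18 macrophage markers, 8 of 11 endothelial markers and 11 of 17 milk genes. They also made up 8 of 29 interferon genes and 6 of 26 NF-kB genes. A lack of calls among them need not mean unchanged expression.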

Other observations

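Peroxisomal, branched-chain amino acid, thermogenic and matrix genes had lower medians in sXBP1 samples, in lists composed after an exploratory fit had been seen; all tests in this part were chosen after results were seen, as were the genes named. Of 30 peroxisome genes 13 fell and 3 rose (median -0.19), with catalase, Cat, down by 1.36 ± 0.06 and Acox2 among those that rose. Of 19 genes of branched-chain amino acid breakdown 7 fell and 0 rose (median -0.18), including Ivd, which fell by 1.19 ± 0.18, and Bckdhb, which fell by 0.92 ± 0.12, while the cytosolic aminotransferase Bcat1 rose by 3.19 ± 0.14. Of 15 thermogenic adipocyte genes 7 fell and 1 rose (median -0.33), with Cidea at -1.45 ± 0.20 and Ppargc1b at -1.32 ± 0.13. Ucp1 was called present on no array and did not pass (0.19 ± 0.13, adjusted p = 0.338). Ppargc1a, counted as a fall, was also present on no array, and Zic1, which rose, had signals of 1.60 in GFP and 10.8 in sXBP1 samples. Cox7a1, Cox8b and Ppargc1a also belong to the oxidative phosphorylation or lipolysis and oxidation lists. Of 10 small leucine-rich matrix proteins 5 fell and 0 rose (median -0.15), among them Aspn at -1.55 ± 0.13 and Lum at -0.97 ± 0.10. Camera adjusted p at the preset correlation was 0.0012, 0.0012, 0.0033 and 0.0042 in that order, and 0.191, 0.191, 0.138 and 0.138 with an estimated correlation, so a joint change of each list stays open.

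Of 11 plasma cell genes 5 rose and 1 fell (median 0.16, camera adjusted p = 0.0033; adjusted p = 0.138 with an estimated correlation), but 4 of the 5, Fkbp11, Sec11c, Creld2 and Edem1, also belong to the ER lists, and the other was Ighm. Sdc1, Irf4, Prdm1, Pou2af1 and Tnfrsf17 did not pass the threshold. Only Sdc1 among them was bright, with signals of 2311 in GFP and 2516 in sXBP1 samples. Irf4, Prdm1, Pou2af1 and Tnfrsf17 had dim group signals, from 3.5 to 22.3, so whether their probe sets could report a change is unknown. Derl3, counted as the fall, was called present on no array. Of 31 proteasome genes 11 rose and 6 fell (median 0.025, camera adjusted p = 0.395). Of 29 lysosome genes 6 rose and 6 fell (median -0.018, camera adjusted p = 0.795), with Ctsh at 1.62 ± 0.12. Of 29 Golgi glycosyltransferase and sulfation genes 5 rose and 2 fell (median -0.022, camera adjusted p = 0.702), with Papss2 at 1.71 ± 0.13. The proteasome, lysosome and Golgi lists thus showed no shift in 1 direction with camera, at the preset or the estimated correlation. The plasma cell list passed only at the preset correlation, so a joint change of its genes stays open. The rule for calling a joint change absent asked for almost no changed members, so it could not be met here.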
